A study of Mus musculus with 27 samples.

How the data were processed

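RNA from 27 libraries of 4T1 cells was measured by polyA RNA sequencing with a KAPA RNA HyperPrep kit. The authors trimmed reads with Trimmomatic 0.35 and quantified genes with RSEM on mouse genome build GRCm38 (mm10), and the version of RSEM and the aligner are not given in the sources used here. The deposited table holds RSEM expected counts per gene for all libraries, with no normalization between libraries. Of its values 91.5% were whole numbers, as were 74.9% of the values above 0, and all were rounded to whole numbers before fitting. Column totals ran from 18492020 to 31295937 counts, and 3 counts over a group were taken as the floor for a gene with 0 counts. Fold ratios of genes with 1 to 3 counts carry 95% counting intervals.

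Libraries were grouped by the column names, which name the knockout, the clone code and the treatment. The groups, the comparisons, the gene lists, the rule for named genes and the alternatives were fixed before the data were examined, except for the alternatives named as added. Column names carry a serial number rather than a replicate number, and replicates were numbered by their order within a group.

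Differential expression was tested in R 4.3.3 with edgeR 4.0.16. The 21 libraries of the knockout arm were fitted together with 1 coefficient per group, and the 6 libraries of the drug arm were fitted alone. Genes were filtered with filterByExpr, which left 13940 genes in the knockout arm and 12603 in the drug arm. TMM factors, the quasi-likelihood F test (two-sided) and Benjamini-Hochberg adjustment over all tested genes were used, with an adjusted p below 0.05 as the threshold. A change was assigned to a genotype where both clones passed with the same sign, and to all 6 clones where all passed with the same sign. The genotypes were compared on counts summed over the 3 libraries of each clone, with 2 sums per genotype and 15513 genes. Levels are CPM, counts scaled to a common total per library, and standard errors of log2 fold changes are those of the fitted coefficients.

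The gene lists covered mitochondrial, metabolic, stress, immune, adhesion and growth themes and markers of other cell types, and those with fewer than 5 tested members were left out. Lists were tested with camera in limma 3.58.1 on voom values with a preset correlation of 0.01 between genes, and adjusted over the lists within each contrast. A genotype's list was called where both clones passed in the same direction. With an estimated correlation between genes, no list called in both clones of Drp1 or Mff or with leflunomide kept its call. The test fry asks whether a list's genes move 1 way on balance and does not compare a list with other genes.

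Genes named in the text were chosen by a rule. For each genotype and for leflunomide it took the 12 higher and 12 lower called genes with the largest change and a mean of at least 5 CPM, by the smaller of the 2 clones. For all 6 clones it took 8 in each direction, and for genotype differences the 8 with the smallest p. It added up to 4 called members of each called list, and always Dnm1l, Fis1, Mff, Mfn1, Mfn2, Opa1 and Dhodh. Genes outside the rule are named as such. The text gives a part of the genes the rule takes. Pgk1-rs7, a gene the rule takes for each genotype, had a larger SD (38.2 CPM) than mean (29.6 CPM) in parental cells and is not named in the report, but it is among the genes counted, including the 23 near 0 in 1 to 5 clones.

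Overlaps were set beside the number that independent lists of the same sizes would share and, for clones, beside 20 simulations of unchanged groups that shared 1 set of control libraries. The whole procedure was tested on simulated data with 200 changed genes. In single clones it recovered 64.6% of genes changed 1.5-fold and 84.0% of those changed 2-fold, with 3.60% of calls false. With leflunomide's design it recovered 48.0% and 77.6%, with 11.2% false.

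The alternatives fixed in advance were DESeq2 1.42.0 in place of edgeR, its size factors in place of the edgeR scaling, no low-count filter, a 2-fold minimum, other fits of the clones, all 27 libraries in 1 fit, an estimated correlation or fry for the lists, and leaving out each library in turn. Alternatives added after the data were seen were the serial run of columns as a block, ribosomal RNA genes left out, limma voom with quality weights, and the gene lists and named genes without DMSO replicate 3. The serial run is a run of consecutive column numbers with 1 library of each group, and nothing says that it was a shared day. Figures were drawn in Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.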

Results

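Polyadenylated RNA was sequenced from 4T1 cells, a mouse mammary carcinoma line, in 27 libraries that fall into 9 groups of 3. The knockout arm held the parental cells and 6 clones made with CRISPR-Cas9, 2 for each of the 3 genotypes: Drp1 (gene Dnm1l, clones gs1B8 and gs2_B4), Fis1 (clones gs1_B11 and gs2_F6) and Mff (clones gs1_B4 and gs1_C8). The drug arm held cells kept for 3 days with leflunomide or with its vehicle DMSO. Clones are named here by their codes, and which code is the first or the second clone of a genotype in the public labels is not stated in the sources used here. Library totals ran from 20715428 to 31295937 counts in the knockout arm and from 18492020 to 24658747 in the drug arm, over 55401 genes. DMSO replicate 3 had 23.2% of its counts in the 45S ribosomal RNA precursor, against 1.60% to 5.72% in the other 26 libraries. Intervals and floors given below cover counting error only. Nothing in the labels says that replicates were separate cultures, so p-values measure only the spread between these samples.

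The first comparison asked whether the targeted transcripts were lower in the clones made to lack them. Dnm1l, which encodes the GTPase that divides mitochondria (ENSMUSG00000022789.15, GRCm38 chromosome 16, 16312230 to 16358959), stood at 220.9 ± 4.4 CPM (SD, n = 3) in parental cells, at 69.0 CPM in gs1B8 and at 41.4 CPM in gs2_B4. Its log2 fold changes were -1.68 ± 0.05 and -2.42 ± 0.05 (SE), with adjusted p of 3e-15 and 1.7e-17. Fis1, a protein of the outer mitochondrial membrane (ENSMUSG00000019054.13, chromosome 5, 136953275 to 136966234), fell from 47.6 ± 4.3 CPM to 21.1 in gs1_B11 and 17.1 in gs2_F6, which left 44.3% and 36.0% of the parental level (adjusted p of 2e-09 and 1.5e-10). Mff, the receptor that recruits Drp1 to mitochondria (ENSMUSG00000026150.14, chromosome 1, 82724890 to 82752394), fell from 85.5 ± 5.4 CPM to 46.5 in gs1_B4 and 42.4 in gs1_C8, or 54.4% and 49.6% of the parental level (adjusted p of 2.3e-10 and 3e-11). RNA level does not show whether protein was made, and protein was not analysed here.

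**Figure D1:**
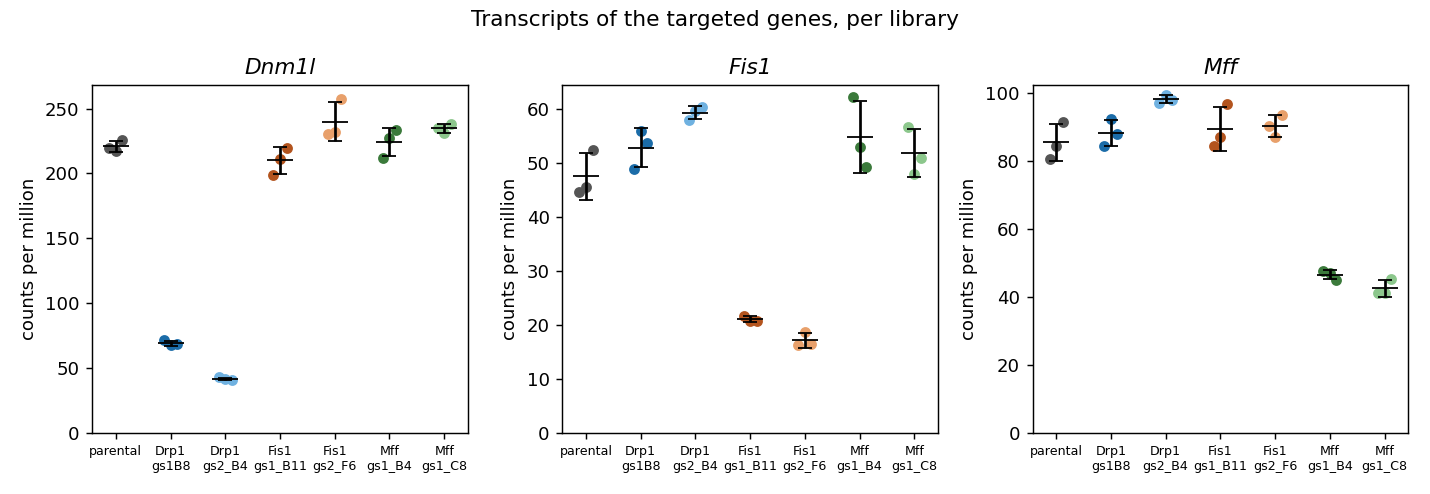
CPM of Dnm1l, Fis1 and Mff in each of the 21 libraries of the knockout arm (points), with the mean and SD of each group (n = 3). Each gene was lowest in the clones made to lack it, with Dnm1l at 69.0 and 41.4 CPM, Fis1 at 21.1 and 17.1 CPM, and Mff at 46.5 and 42.4 CPM.

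The second comparison asked which genes changed in both clones of a genotype against parental cells. In both Drp1 clones, Lrp1, an endocytic receptor, rose from 24.3 ± 2.95 CPM to 93.7 and 207.8 CPM (log2 1.95 ± 0.11 and 3.09 ± 0.11, SE, n = 3). Selp, the adhesion receptor P-selectin, rose from 2.35 to 16.2 and 23.8 CPM, Ckap4, an endoplasmic reticulum membrane protein, from 16.6 to 48.7 and 91.1 CPM, and the granzyme inhibitor Serpinb9 from 25.1 to 94.1 and 86.3 CPM. Ap1m2, a subunit of an epithelial sorting adaptor, had 0 counts in both clones and was at least 585-fold and 605-fold lower against a floor of 3 counts over the group. The tight-junction gene Cldn3 also had 0 counts, at least 411-fold and 425-fold lower. Mal2, which acts in apical transport, was 2500-fold lower in gs1B8 (95% counting interval 692 to 20700) and 1720-fold lower in gs2_B4 (590 to 8370). Rab25, an epithelial recycling GTPase, fell by 1.33 and 1.69 on the log2 scale, and Nox4, an NADPH oxidase, by 4.83 and 5.47. Dhodh, the enzyme that leflunomide inhibits, fell by 0.53 ± 0.06 and 0.72 ± 0.07 (adjusted p of 3.5e-06 and 1.7e-08), and the fusion GTPase gene Opa1 by 0.20 ± 0.04 in each. Mfn2, another fusion gene, had log2 fold changes of -0.17 and -0.20 (adjusted p of 0.034 and 0.0061), a call that was lost without parental replicate 1 (-0.14) or 2 (-0.16), without gs1B8 replicate 1 (-0.19), 2 (-0.19) or 3 (-0.18), or without gs2_B4 replicate 2 (-0.18), and also without the low-count filter (-0.17) or with ribosomal RNA genes left out (-0.16), the values being means of the clones. Mfn1 had log2 fold changes of 0.01 in gs1B8 (adjusted p = 0.88) and -0.36 in gs2_B4.

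Of the fixed gene lists, 6 shifted in both Drp1 clones. Among 35 integrin and focal adhesion genes, 14 rose and 3 fell in both clones (15 and 3 when adjusted over the list alone), with list medians of 0.19 and 0.26. Fermt2, an integrin activator, rose from 69.1 to 114.9 and 145.3 CPM, and Itgb3 from 0.787 to 4.32 and 6.42 CPM. Among 20 genes of MHC class I antigen presentation, 7 rose in both (7 adjusted over the list alone), including the proteasome activator Psme1 (log2 0.82 and 1.05), H2-K1 (0.45 and 0.58) and H2-D1 (0.38 and 0.43). Of 21 genes of the endoplasmic reticulum unfolded protein response, 7 rose in both (7 adjusted over the list alone), with the chaperone gene Hyou1 at log2 0.36 and 0.57 and the co-chaperone Dnajc3 at 0.50 and 0.33. Of 13 mRNAs encoded by mitochondrial DNA, 4 rose in both (4 adjusted over the list alone), with mt-Nd1 at log2 0.30 and 0.37 and mt-Nd2 at 0.38 and 0.55. Of 32 DNA replication and E2F target genes, 13 fell in both clones (15 adjusted over the list alone). The helicase subunit gene Mcm5 fell from 286.6 to 197.6 and 149.3 CPM, and the transcription factor gene E2f1 from 36.8 to 24.9 and 20.7 CPM. Of 29 genes of mitosis, 8 fell in both (7 adjusted over the list alone), with the mitotic kinase Plk1 at log2 -0.21 and -0.33. The larger camera adjusted p of the clones was 0.0071 for integrins, 0.048 for MHC class I, 0.029 for the unfolded protein response, 0.026 for mitochondrial mRNAs, 0.0071 for replication and 0.038 for mitosis. With an estimated correlation the larger adjusted p was 0.71, 0.79, 0.71, 0.69, 0.34 and 0.43 in the same order. Of the 26 genes of mitochondrial fission and fusion that were tested, 5 fell and 0 rose in both clones (6 and 0 adjusted over the list alone), and the list was not called (larger adjusted p = 0.65, and 0.91 with an estimated correlation). The list of 38 epithelial junction and keratin genes was not called either, with 4 higher and 6 lower in both clones (4 and 6 adjusted over the list alone; larger adjusted p = 0.19, and 0.71 with an estimated correlation). The integrin and replication calls were kept with DESeq2 size factors, without ribosomal RNA genes and with each library of the comparison left out. The MHC class I call was lost in each of these (larger adjusted p from 0.05 to 0.078). The mitosis call was lost with DESeq2 size factors (0.064), without ribosomal RNA genes (0.089), and without parental replicate 1 (0.059), 2 (0.07) or 3 (0.058), gs1B8 replicate 1 (0.059) or gs2_B4 replicate 2 (0.055). The unfolded protein response was lost without parental replicate 1 (0.065) or gs1B8 replicate 3 (0.056), and mitochondrial mRNAs without parental replicate 3 (0.057). The test fry called neither the MHC class I nor the unfolded protein response list in both Drp1 clones.

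Across all genes, 4109 changed in gs1B8 (1685 higher, 2424 lower) and 7017 in gs2_B4 (3357 higher, 3660 lower), of 13940 tested. In both clones with the same sign 1107 genes rose and 1682 fell, 2789 in all, against 405.8 and 636.4 for independent lists, while 289 had opposite calls. Clones of different genotypes shared from 1507 (gs1B8 with gs1_C8) to 4171 (gs2_B4 with gs1_B11) genes of the same sign, so such a count is not particular to a genotype. In simulations of unchanged groups against shared controls, which called a mean of 0.04 genes per clone, the highest count in both clones of a pair was 0. No gene was changed in these simulations, so a count near 0 was almost fixed in advance. Part of the excess may still come from the shared parental libraries, here and for the other genotypes. With the clone as the replicate, the parental libraries form a single sum, so the control has no spread of its own. Counts of calls from that fit are not given. The calls in both clones rest on the spread between libraries, not on that between clones.

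In both Fis1 clones, Mmp9, a secreted protease that cleaves basement membrane, rose from 85.4 ± 8.54 CPM to 374.9 and 375.3 CPM (log2 2.13 ± 0.15 and 2.14 ± 0.15, SE, n = 3). The basal keratin gene Krt14 rose from 63.6 to 200.6 and 205.1 CPM, the caveolar coat gene Cav1 from 43.8 to 103.5 and 136.1 CPM, and Tnfrsf26, a receptor of the tumour necrosis factor family, from 11.2 to 60.0 and 124.4 CPM. Vcam1, an adhesion molecule for leukocytes, fell from 27.7 to 8.27 and 5.92 CPM, the chemokine gene Cxcl3 from 21.6 to 1.69 and 6.92 CPM, and St3gal6, a sialyltransferase, from 22.8 to 4.10 and 4.27 CPM. Cldn3 had 0 counts in both clones, at least 392-fold and 428-fold lower. Ap1m2 was at least 558-fold lower in gs1_B11 and 1830-fold lower in gs2_F6 (95% counting interval 327 to 72200). Cavin2, a caveolar protein, fell by 3.28 on the log2 scale in gs1_B11 and was 615-fold lower in gs2_F6 (210 to 2980). Dhodh had log2 fold changes of -0.28 and -0.20 (adjusted p of 0.0013 and 0.021), a call lost without parental replicate 1 (-0.18) or 2 (-0.22) and without gs2_F6 replicate 1 (-0.23) or 2 (-0.24), as well as without the low-count filter (-0.23) and with DESeq2 (-0.23), the values being means of the clones. Mfn1 had log2 fold changes of -0.43 in gs1_B11 and 0.04 in gs2_F6 (adjusted p = 0.46), and Opa1 of -0.23 and 0.08 (adjusted p of 0.00011 and 0.14). Of the 26 fission and fusion genes, 3 rose and 3 fell in both clones (3 and 3 adjusted over the list alone).

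Camera called 0 gene lists in both Fis1 clones with either correlation, and fry called 9. The mitochondrial mRNAs, called for Drp1 at medians of 0.26 and 0.30, had medians of 0.43 and 0.31 here, with 4 of 13 higher in both clones. That list, the integrins (0.24 and 0.035) and the epithelial genes (0.27 and 0.13) each had a larger camera adjusted p of 0.059 (0.95 with an estimated correlation). Without 1 library the number of lists called by camera was 3 without parental replicate 1, 2 without parental replicate 2, 1 without parental replicate 3, 3 without gs1_B11 replicate 1, 2 without gs1_B11 replicate 3, and 1 without gs2_F6 replicate 1, 2 or 3. Genes changed numbered 6594 in gs1_B11 (2980 higher, 3614 lower) and 4365 in gs2_F6 (1826 higher, 2539 lower). In both clones 828 rose and 1258 fell, 2086 in all, against 390.4 and 658.2 for independent lists and 0 in the simulations, and 738 had opposite calls. With the Drp1 clones gs1B8 and gs2_B4, gs1_B11 shared 2912 and 4171 genes of the same sign, and gs2_F6 shared 1916 and 1923. Such a count is therefore not particular to the genotype. These calls too rest on the spread between libraries, since the parental control is a single sum with the clone as the replicate.

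In both Mff clones, S100a4, a calcium-binding protein studied for its part in metastasis, fell from 639.0 ± 74.7 CPM to 75.8 and 65.1 CPM (log2 -3.08 ± 0.13 and -3.30 ± 0.13, SE, n = 3). The leukocyte integrin gene Itgb2 fell from 16.6 to 1.71 and 1.58 CPM, Cav1 from 43.8 to 7.82 and 3.35 CPM, and Sparc, a matrix protein, from 68.9 to 27.4 and 7.23 CPM. Cldn3 had 0 counts in gs1_B4, at least 440-fold lower, and 1 count in gs1_C8, 1270-fold lower (95% counting interval 227 to 50100). Selp rose from 2.35 to 22.3 and 44.2 CPM. Lgals9, which encodes a secreted lectin, rose from 8.25 to 32.4 and 139.4 CPM, and Oasl1, an interferon-induced gene, from 7.04 to 24.5 and 78.4 CPM. Mfn2 moved apart in the clones, at log2 -0.17 in gs1_B4 and 0.27 in gs1_C8 (adjusted p of 0.019 and 0.00065), and Dhodh fell by 0.30 and 0.25.

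Of the fixed lists, 6 shifted in both Mff clones. Of 34 interferon-stimulated genes, 19 rose in both (19 adjusted over the list alone), with a median log2 fold change of 0.74 in gs1_B4 and 4.58 in gs1_C8. Ifit1, an RNA-binding antiviral effector, rose from 2.37 to 7.41 and 98.1 CPM, the RNA sensor gene Ifih1 from 36.7 to 65.7 and 189.8 CPM, and Usp18, which removes ISG15 from proteins, from 0.840 to 3.13 and 64.9 CPM. Of 28 cytokine, chemokine and NF-kappaB target genes, 13 rose and 1 fell in both (14 and 1 adjusted over the list alone), with Cxcl10 at log2 1.20 and 4.47 and Il23a at 0.79 and 0.74. Of 19 genes of glycolysis and lactate export, 8 fell and 1 rose in both (9 and 1 adjusted over the list alone), with Pgam1 at log2 -0.64 and -0.79 and the rate-controlling enzyme gene Pfkl at -0.56 and -0.59. Of 20 purine synthesis genes, 8 fell in both (8 adjusted over the list alone), with Prps1, which makes the shared nucleotide precursor, at log2 -0.93 and -0.35. Of 36 genes of MYC and ribosome biogenesis, 17 fell in both (19 adjusted over the list alone), with the nucleolar gene Nolc1 at log2 -0.47 and -0.38. Of 29 mitosis genes, 15 fell in both (15 adjusted over the list alone), with the spindle motor gene Kif11 at log2 -0.53 and -0.46 and the cyclin gene Ccna2 at -0.31 and -0.41. The larger camera adjusted p was 0.0071 for interferon, 0.0051 for cytokines, 0.045 for glycolysis, 0.016 for purines, 0.0013 for ribosome biogenesis and 0.0051 for mitosis. With an estimated correlation the larger adjusted p was 0.86, 0.86, 0.86, 0.50, 0.50 and 0.54 in the same order. The test fry did not call the interferon list in both Mff clones. The glycolysis call was lost with DESeq2 size factors (0.055), without ribosomal RNA genes (0.056), and without parental replicate 3 (0.11), gs1_B4 replicate 2 (0.064) or gs1_C8 replicate 1 (0.054) or 3 (0.053). Of the 26 fission and fusion genes, 1 rose and 5 fell in both clones (1 and 5 adjusted over the list alone), and the list was not called (larger adjusted p = 0.82, and 0.93 with an estimated correlation).

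**Figure D2:**
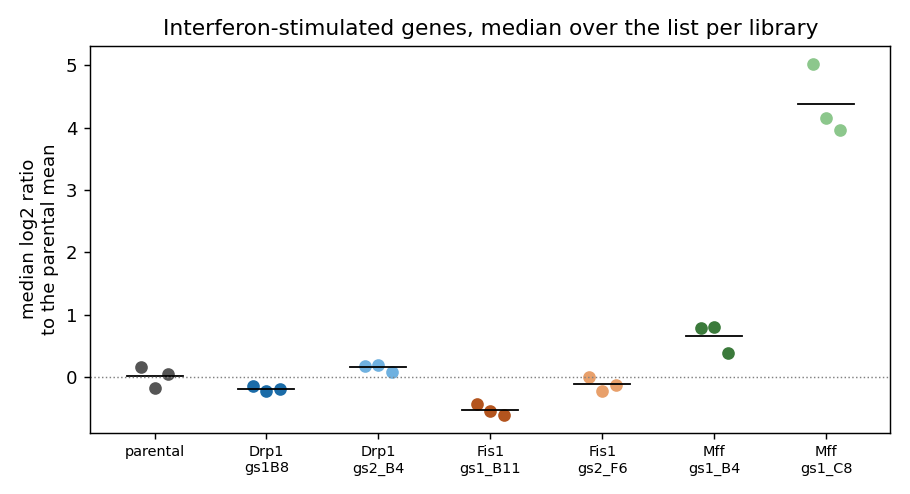
Median log2 ratio to the parental mean over the interferon-stimulated genes, per library (points), with bars at the mean of the library medians of each group (n = 3). The gs1_C8 libraries sit between 3.97 and 5.03 and the gs1_B4 libraries between 0.39 and 0.81.

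Genes changed numbered 6647 in gs1_B4 (2916 higher, 3731 lower) and 6509 in gs1_C8 (3001 higher, 3508 lower). In both clones 1027 rose and 1571 fell, 2598 in all, against 627.8 and 938.9 for independent lists and 0 in the simulations, and 1211 had opposite calls. With the Drp1 clones gs1B8 and gs2_B4, gs1_B4 shared 2111 and 3362 genes of the same sign, and gs1_C8 shared 1507 and 2715. As for Drp1 and Fis1, these calls rest on the spread between libraries and not on that between clones.

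The third comparison asked what the 3 genotypes shared. In all 6 clones 75 genes rose and 293 fell, 368 in all. Selp rose in each, from 6.001 CPM in gs2_F6 to 44.2 CPM in gs1_C8 against 2.35 ± 0.173 in parental cells (SD, n = 3). The interferon-inducible gene Gbp2 rose to between 4.87 and 35.0 CPM from 2.77, and the chromatin remodeller gene Chd7 to between 21.8 and 37.1 CPM from 12.8. Gbp2b, a guanylate-binding gene, was called in all 6 clones (largest adjusted p = 0.04), a call lost without parental replicate 1, 2 or 3 (mean log2 fold changes of 1.84, 1.80 and 1.64). Scoc fell from 140.5 to between 55.1 and 99.5 CPM, the replication gene Gins3 from 34.1 to between 16.9 and 24.4 CPM, and the inositol transporter gene Slc5a3 from 51.8 to between 23.8 and 37.5 CPM. Independent lists of these sizes would share 0.51 genes higher and 2 lower. In 20 simulations of unchanged groups against shared controls the highest all-6 count was 0, and part of the excess over independent lists may still come from the shared controls, since 3 parental libraries cannot be split among 6 clones. The mean Pearson r of log2 fold changes across genes over the 15 clone pairs was 0.36, against 0.515 in the simulations, and the mean covariance was 0.2896 against 0.0422. Genes are not independent replicates, so these values are descriptions.

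**Figure D3:**
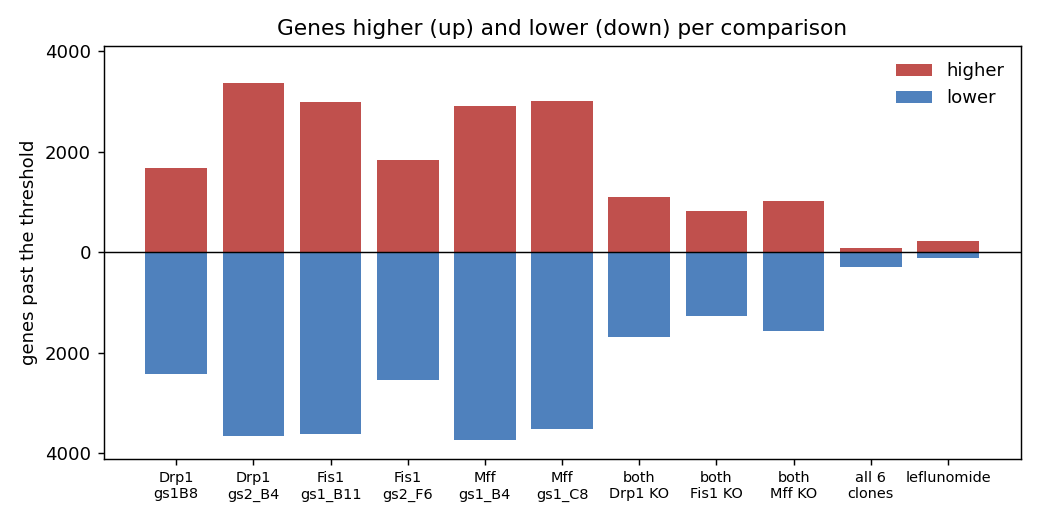
Number of genes higher (above 0) and lower (below 0) at an adjusted p under 0.05 in each clone, in both clones of a genotype, in all 6 clones and with leflunomide. Both clones shared 2789 genes for Drp1, 2086 for Fis1 and 2598 for Mff, and all 6 shared 75 higher and 293 lower.

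The fourth comparison asked whether the genotypes differed from each other, with the 2 clones of each genotype as replicates. The edgeR quasi-likelihood F test called 0 of 15513 genes, with 872 at an unadjusted p under 0.05, and the DESeq2 likelihood ratio test called 321. Without the low-count filter edgeR called 49. In the pairwise contrasts of the same fit, only Ppp1r9a, an actin-binding scaffold gene of neurons, passed: it was higher in Drp1 than Mff clones by log2 5.88 ± 0.29 (adjusted p = 0.028) and in Fis1 than Mff clones by 5.84 ± 0.29 (adjusted p = 0.029), and its F test gave an adjusted p of 0.075. Ppp1r9a was named after its values were seen. It stood at 12.7 CPM in parental cells, at 19.6 and 21.9 in the Drp1 clones, at 24.2 and 16.6 in the Fis1 clones, and at 0.373 and 0.315 in the Mff clones. The biological coefficient of variation was 32.8% between clones of a genotype and 6.80% between libraries of a group. Clones of 1 genotype had a mean r of 0.422 across genes (Drp1 0.448, Fis1 0.522, Mff 0.296), against 0.345 for other pairs. An exact permutation test over the 15 ways to pair the clones gave a one-sided p of 0.2, where 0.067 is the smallest it allows. Clones of 1 genotype shared a mean of 2491 genes called with the same sign and other pairs 2401.9, and the same test gave a p of 0.333. In simulated data with a 4-fold change this design recovered 54.0% of changed genes, and with a 2-fold change 4.10%. Over all the simulated changes 13.9% of its calls were false.

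The fifth comparison asked what leflunomide, an inhibitor of pyrimidine synthesis at Dhodh, changed after 3 days. Bnip3, a mitophagy receptor induced by low oxygen, fell from 27.2 ± 2.08 to 10.02 CPM (log2 -1.44 ± 0.10, SE, n = 3, adjusted p = 0.0015). Pdk1, a kinase that limits pyruvate entry into mitochondria, fell from 39.4 to 22.2 CPM, and Pfkl and Pfkp, phosphofructokinase genes, from 155.1 to 90.4 and from 56.6 to 33.6 CPM. Klf2, a transcription factor gene, rose from 1.87 ± 0.466 to 13.5 CPM (log2 2.84 ± 0.20, adjusted p = 0.0015) and the GTPase gene Rhob from 43.6 to 169.4 CPM. The chemokine gene Ccl2 rose from 2.73 to 10.9 CPM and the matrix gene Tnc from 3.91 to 12.6 CPM. None of the fission and fusion genes named here passed the test, with log2 fold changes of -0.01 for Dnm1l (adjusted p = 0.95), 0.24 for Fis1 (0.33), -0.02 for Mff (0.91), -0.13 for Mfn1 (0.29), 0.04 for Mfn2 (0.79) and -0.02 for Opa1 (0.91). Dhodh was at -0.24 ± 0.10 (adjusted p = 0.23). With quality weights Fis1 passed (0.32), and with all 27 libraries in 1 fit Mfn1 (-0.13) and Dhodh (-0.24) passed.

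Of the 38 gene lists tested, 17 shifted with leflunomide by camera, while the test fry called 4. Splits that mixed the leflunomide and DMSO libraries called from 7 to 17 lists. A camera adjusted p at the preset correlation therefore does not by itself set the treatment apart. Of 25 hypoxia and HIF target genes, 7 fell and 0 rose over all genes (14 and 1 adjusted over the list alone), with a median of -0.24, an adjusted p of 9e-08, and an adjusted p of 0.14 with an estimated correlation. Kdm3a, a histone demethylase induced by hypoxia, fell by 0.65 on the log2 scale. Of 19 genes of glycolysis and lactate export, 5 fell (12 adjusted over the list alone), with Ldha at log2 -0.54, a list adjusted p of 9e-08, and an adjusted p of 0.14 with an estimated correlation. Of 21 unfolded protein response genes, 10 rose (15 adjusted over the list alone; adjusted p = 3.8e-10, and 0.38 with an estimated correlation). The chaperone gene Hspa5 rose from 1826 to 3073 CPM and its partner Dnajb9 from 12.5 to 20.5 CPM. Of 30 interferon-stimulated genes, 4 rose (15 adjusted over the list alone), with a median of 0.83 (0.52 without leflunomide replicate 3), Isg15 at log2 1.02, an adjusted p of 2.7e-12, and an adjusted p of 0.45 with an estimated correlation. Of 24 cytokine, chemokine and NF-kappaB target genes, 6 rose (17 adjusted over the list alone), with Nfkbia at log2 0.58, an adjusted p of 3.8e-10, and an adjusted p of 0.45 with an estimated correlation. Of 23 mesenchymal genes, 7 rose (10 higher and 2 lower adjusted over the list alone; adjusted p = 8.3e-05, and 0.27 with an estimated correlation), with a median of 0.31, or 0.14 without leflunomide replicate 3. The fibronectin gene Fn1 rose from 490.2 to 882.6 CPM and Inhba from 134.3 to 265.6 CPM. Of 35 epithelial junction and keratin genes, 2 fell (8 adjusted over the list alone; adjusted p = 5.8e-05, and 0.38 with an estimated correlation), Krt7 at log2 -0.58 and Ocln at -0.56. Of 31 immediate early and heat shock genes, which respond to handling, 6 rose (12 adjusted over the list alone; adjusted p = 9.4e-06, and 0.45 with an estimated correlation), with Jun at log2 0.88. Of 24 YAP and TEAD targets, 4 rose (9 adjusted over the list alone; adjusted p = 0.024, and 0.69 with an estimated correlation), including Ccn1 at log2 0.90. This list had a median of 0.06, or 0.09 without leflunomide replicate 2, and was not called without DMSO replicate 2 (adjusted p = 0.079) or leflunomide replicate 3 (0.04, adjusted p = 0.43).

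Among the other 8 called lists, DNA replication and E2F targets had a median of 0.16 (0.10 without leflunomide replicate 1, 0.25 without leflunomide replicate 3) and 2 of 32 higher (8 adjusted over the list alone), and MHC class I had 0.29 and 2 of 20 higher (11 adjusted over the list alone). Nuclear-encoded respiratory complex I subunits had a median of 0.16 with 0 of 36 past the test, and complexes II to V had 0.09 with 0 of 35, each with 0 when adjusted over the list alone. Extracellular proteases and inhibitors had 0.20, with 3 of 27 higher and 1 lower (5 and 1 adjusted over the list alone; adjusted p = 0.047), and this list was not called without DMSO replicate 1 (0.14, adjusted p = 0.067), 2 (0.17, adjusted p = 0.076) or 3 (0.16, adjusted p = 0.066) or without leflunomide replicate 1 (0.14, adjusted p = 0.11) or 2 (0.13, adjusted p = 0.1). Targets of ATF4 had -0.12 with 1 of 24 higher and 1 lower (1 and 6 adjusted over the list alone), NRF2 genes had -0.14 with 1 of 32 lower (1 adjusted over the list alone), and fatty acid synthesis had -0.09 with 0 of 15 (2 lower adjusted over the list alone). Complexes II to V were not called without DMSO replicate 1 (0.06, adjusted p = 0.067) and had 0.14 without DMSO replicate 2. The ATF4 list was not called without DMSO replicate 2 (-0.07, adjusted p = 0.076) or leflunomide replicate 3 (-0.13, adjusted p = 0.056), nor the NRF2 list without DMSO replicate 2 (-0.09, adjusted p = 0.076) or leflunomide replicate 3 (-0.10, adjusted p = 0.14). Fatty acid synthesis was not called without DMSO replicate 1 (-0.06, adjusted p = 0.16) or leflunomide replicate 3 (0.04, adjusted p = 0.96), and had -0.15 and -0.14 without leflunomide replicates 1 and 2. Without ribosomal RNA genes neither the proteases (adjusted p = 0.069) nor fatty acid synthesis (0.051) were called, and fatty acid synthesis was not called with the serial run as a block (0.067). With an estimated correlation the adjusted p of these 8 lists lay between 0.38 and 0.69. The pyrimidine synthesis and salvage list, which holds Dhodh, had a median of 0.08 and 0 of 23 members past the test (0 adjusted over the list alone; adjusted p = 0.21, and 0.69 with an estimated correlation). Its median was 0.11, 0.14 and 0.04 without DMSO replicates 1, 2 and 3 (adjusted p of 0.27, 0.076 and 0.38) and 0.06, 0.06 and 0.14 without leflunomide replicates 1, 2 and 3 (adjusted p of 0.46, 0.21 and 0.056).

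**Figure D4:**
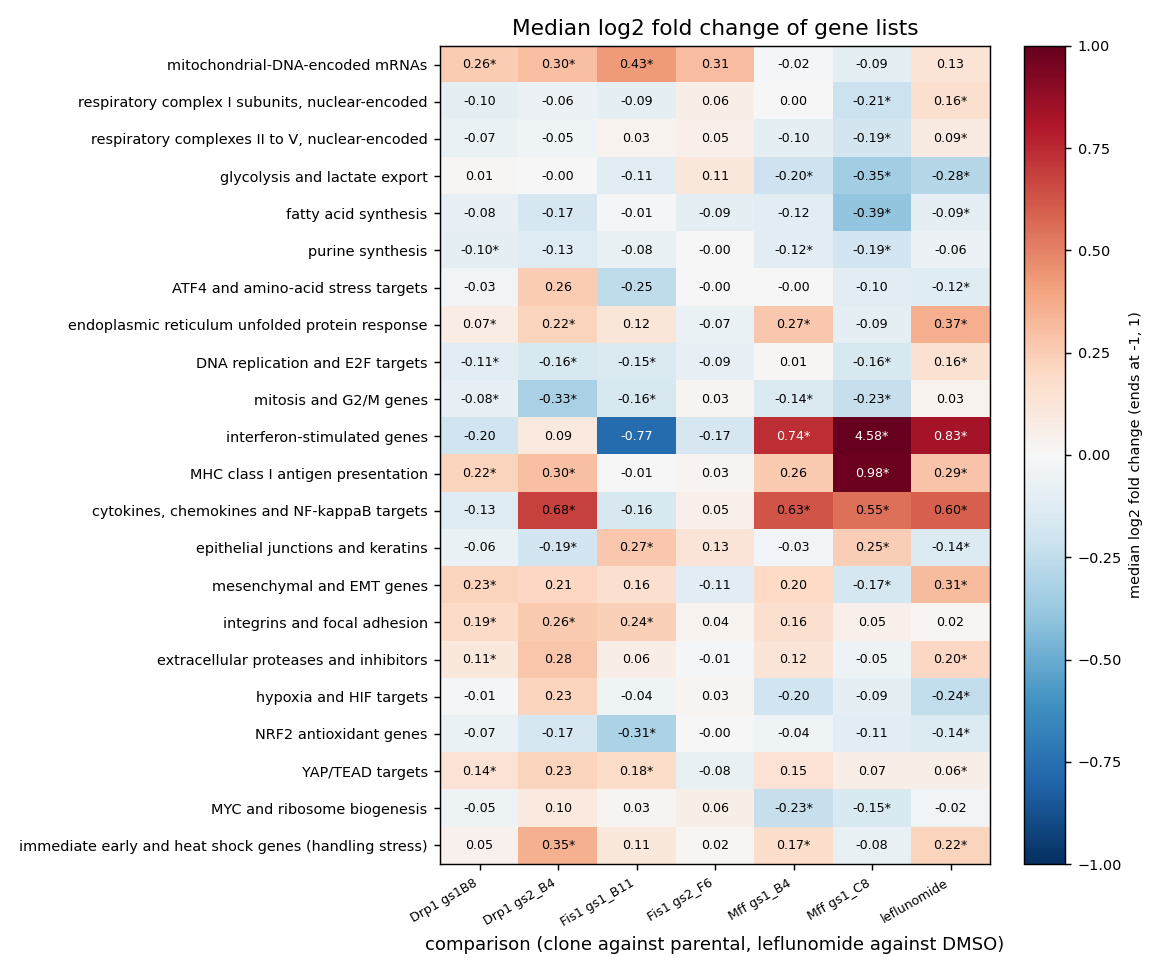
Median log2 fold change of the gene lists called in both clones of a genotype or with leflunomide (vertical axis), for each clone against parental and for leflunomide against DMSO (horizontal axis), with an asterisk where the camera adjusted p was below 0.05. The interferon list stands at 4.58 in gs1_C8 and at 0.83 with leflunomide, and hypoxia targets at -0.24 with leflunomide.

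**Figure D5:**
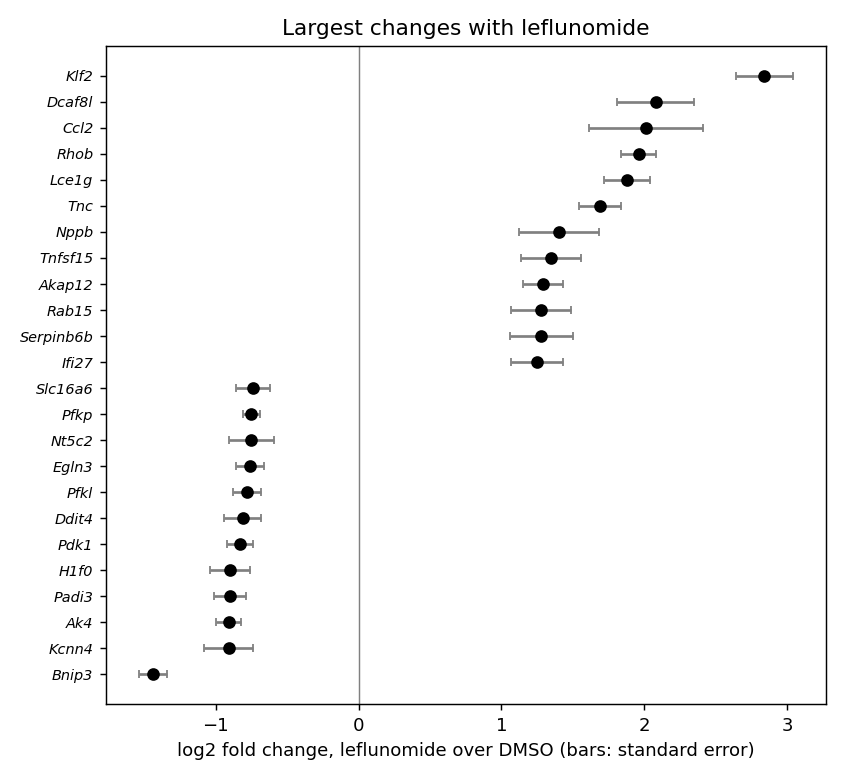
Log2 fold change with leflunomide against DMSO (points) with its SE (bars) for genes chosen by the naming rule, n = 3 per group. Klf2 stands highest at 2.84 and Bnip3 lowest at -1.44.

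In all, 351 of 12603 genes changed with leflunomide, 232 higher and 119 lower, 62 of them by at least 2-fold, and 2634 had an unadjusted p under 0.05. The count was 13 without DMSO replicate 1, 26 without DMSO replicate 2, 166 without DMSO replicate 3, 120 without leflunomide replicate 1, 10 without leflunomide replicate 2 and 1583 without leflunomide replicate 3. All 351 genes kept their direction in each of these fits, which was almost fixed in advance, since they were called with all 6 libraries. Of the genes named first for this comparison, Bnip3, Pfkp, Klf2, Rhob and Tnc kept their calls in each. The call of Ccl2 under leflunomide was lost without DMSO replicate 1 (1.86), 2 (2.03) or 3 (2.17) or leflunomide replicate 2 (2.20). That of Pfkl under leflunomide was lost without DMSO replicate 1 (-0.76) or 2 (-0.81) or leflunomide replicate 2 (-0.76), and that of Pdk1 under leflunomide without DMSO replicate 1 (-0.80) or leflunomide replicate 2 (-0.755). Of the list members named, Jun lost its call without leflunomide replicate 2, Kdm3a and Fn1 without that library or DMSO replicate 1, and Ldha, Hspa5, Dnajb9, Nfkbia, Inhba, Krt7 and Ccn1 without either of these or DMSO replicate 2. Isg15 lost it without any of these 3 or leflunomide replicate 1, and Ocln without any library except leflunomide replicate 3.

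The sixth comparison asked whether leflunomide and the knockouts moved the same genes. With Mff, 96 genes changed the same way, 61 higher and 35 lower, against 17.7 and 14.5 for independent lists, and 18 changed in opposite ways, against 9 and 28.3 for the opposite directions. Bnip3 was lower in both (mean log2 -0.80 in the Mff clones), as were Pfkl (-0.58) and Ddit4 (-1.25), and Isg15 (2.43), Lgals9 (3.03), Cxcl10 (2.84) and Ccn2 (0.79) were higher in both. These shared genes were named after their values were seen. Under leflunomide the calls of Ddit4, Ccn2 and Cxcl10 were lost without DMSO replicate 1 (log2 -0.84, 0.75 and 1.42), DMSO replicate 2 (-0.85, 0.78 and 1.42) or leflunomide replicate 2 (-0.84, 0.86 and 1.49), and that of Cxcl10 also without DMSO replicate 3 (1.45). The call of Lgals9 was kept only without leflunomide replicate 3 (0.59), with 0.64 to 0.82 in the other fits. With Drp1, 73 genes changed the same way (51 higher, 22 lower, against 19.2 and 15.5) and 51 in opposite ways (against 9.8 and 30.3). With Fis1, 24 changed the same way (13 higher, 11 lower, against 14.7 and 11.3) and 39 in opposite ways (against 7.5 and 22.1). Across the 12590 genes tested in both arms, Pearson r of the log2 fold changes was 0.045 for Mff, -0.003 for Drp1 and -0.128 for Fis1, and Spearman rho was 0.157, 0.067 and -0.071. Genes are not independent replicates, and differences between genotypes in these overlaps were not tested. For Drp1, Fis1 and Mff the counts were 5, 1 and 3 without DMSO replicate 1, and 9, 3 and 4 without DMSO replicate 2. They were 44, 11 and 54 without DMSO replicate 3, and 30, 7 and 43 without leflunomide replicate 1. They were 4, 1 and 2 without leflunomide replicate 2, and 212, 104 and 256 without leflunomide replicate 3.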

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

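The tests chosen only after the result was seen were those of clone isolation, of leflunomide replicate 3, of ribosomal RNA without the library with most of it, of equal strength in the Mff clones in both forms, and of all leukocyte markers against parental cells.

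Several genes that were called in both clones of 2 genotypes moved in opposite directions. These differences were noted because every library of 1 genotype moved 1 way and every library of the other the opposite way, and the F test on the clone sums passed for none of the genes. Lrp1 was higher in the Drp1 than in the Mff clones by a mean log2 difference of 4.22 (adjusted p = 0.72). Dapk1, a kinase of cell death, was higher by 8 in the Drp1 and by 7.69 in the Fis1 than in the Mff clones (adjusted p = 0.2), with gs1_B4 (1 count) at the limit of its 95% counting interval nearest to parental cells and gs1_C8 (0 counts) at the floor of 3 counts over the group. The difference of Fam111a, a nuclear protease gene, was -5.81 between the Drp1 and Mff clones, with gs1B8 (3 counts) at the same limit and gs2_B4 at 25.6 CPM, or -2.94 on the clone sums, and -1.81 between the Fis1 and Mff clones (adjusted p = 0.92). Cntfr was higher in the Fis1 than in the Mff clones by 2.66 (adjusted p = 0.65), and Cav1 by 4.53 (adjusted p = 0.31). The difference of Oasl1 was -4.06 between the Drp1 and Mff clones and -4.24 between the Fis1 and Mff clones (adjusted p = 0.57).

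The first pattern weighed was the set of 368 genes changed alike in all 6 clones, which share their parental libraries. Over these genes the DMSO mean lay at a median position of 0.06 between parental (0) and the clones (1). The 3 DMSO libraries had -0.01, 0.05 and 0.16. This argues against a state of the parental cultures that the DMSO cultures lacked. The DMSO mean lay nearer to parental cells than to the clones for 346 of the 368 genes. That argues against chance values of the parental libraries as the whole cause. The 20 simulations of unchanged groups gave at most 0 such genes but cannot decide this. No gene in them was changed, so the adjusted threshold passed almost none. Isolation as clones and exposure to Cas9, with no part of the genotype, stayed open: pairs of 1 genotype were not more alike at an exact p of 0.2 over 15 pairings, and no unedited clone was analysed here. A shared effect of losing fission proteins, which the design gives as the biological explanation, may also account for the set and was not tested apart from it. Of 30 splits of the libraries 1, the real one, gave as many genes (368, highest other 0). This cannot test chance, since mixing the groups puts the difference between clones into the spread.

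The second pattern was the lower hypoxia and glycolysis genes and the higher interferon genes with leflunomide, in an arm where 1 library left out moved the count of changed genes to between 10 (without leflunomide replicate 2) and 1583 (without leflunomide replicate 3). DMSO replicate 3 alone is argued against, since without it the hypoxia, glycolysis and interferon medians were -0.27, -0.28 and 1.06, each at 97.9% or more of its size and still called at the preset correlation (adjusted p of 0.2, 0.2 and 0.46 with an estimated one), and leflunomide replicate 3 as the whole cause likewise, with -0.28, -0.28 and 0.52, though the interferon median fell to 62.2% of its size. Leaving out the ribosomal RNA genes gave 349 genes but hardly moved the fold changes (median shift -0.0073), so it decides nothing, while the medians without DMSO replicate 3, at 97.9% or more, argue against the high ribosomal RNA share of that library as the whole cause. Differences between cultures that went with the treatment, such as density or handling, and an effect of the drug itself were not tested apart. Splits of 3 against 3 libraries are too few for a share under 0.05, with 351 genes in the real split (1 of 10) and 2 as the highest other.

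The third pattern was the rise of interferon-stimulated genes in both Mff clones, by far more in gs1_C8 than in gs1_B4, with a median difference of 3.7 on the log2 scale. By the test written first, camera with an estimated correlation, equal strength in both clones stayed undecided at this difference (adjusted p = 0.7, and 3.3e-20 with the preset correlation). Gene by gene, with libraries as replicates, edgeR found 34 of 34 members higher in gs1_C8 at an adjusted p below 0.05. By that test 7626 of all 13940 genes differed between these clones in either direction, and list members are not independent. For these 2 clones the size and shared direction of the difference argue against the loss of Mff at equal strength as the whole cause. A single gs1_C8 library is argued against by the lowest library median of 3.97. For immune cells in the cultures the criterion written first was met, with Cd14 at 10.2 CPM in gs1_C8, but parental cells had 7.18 CPM, and over all 26 leukocyte markers 21 were below 0.1 CPM and 0 were above both 1 CPM and 2 times parental, which argues against them. An effect of Mff loss that differs in strength, or a change particular to the gs1_C8 cells, may account for the difference and was not tested further.

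For single clones against parental cells, splits of 3 against 3 libraries are too few for a share under 0.05. In fits of only the libraries compared, 1 of 10 splits, the real one, gave as many genes: 4111 in gs1B8, 6806 in gs2_B4, 6155 in gs1_B11, 3789 in gs2_F6, 5410 in gs1_B4 and 5991 in gs1_C8, where the highest other was 0, or 1 for gs2_F6. For both clones of Drp1, 2 of 50 splits gave as many genes as the real one (2980, highest other 3164, with gs2_B4 whole in the place of the control). For Fis1 1 of 50 did (1943, highest other 649, with gs2_F6 whole as the control), and for Mff 1 of 50 (2102, highest other 1986, with gs1_C8 whole as the control). These shares cannot test chance, since mixing the groups puts the difference between clones into the spread. Splits that kept no group whole gave at most 0 genes, and those that kept a clone whole as the control gave many. A split with the parental libraries whole and the clones mixed gave 1294 genes for Drp1 and 462 for Mff. These counts point to a structure of the samples. Chance was not excluded for the numbers of gene lists, and these mixed splits cannot test it there either. As many lists came from 10 of 50 splits for Drp1 (5, highest other 9) and 22 of 50 for Mff (6, highest other 10). For Fis1 the real number was 0, so 50 of 50 splits were as large by construction (highest other 13). With leflunomide 10 splits are too few for a share under 0.05, both for the lists (17, with 2 of 10 splits as large and a highest other of 17) and for the genes shared with Drp1 (73), Fis1 (24) and Mff (96), each with 1 of 10 splits as large and a highest other of 0.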

How the results depend on the processing

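The tests chosen only after the data were seen were the serial run as a block, ribosomal RNA genes left out, limma with quality weights, and the gene lists and named genes without DMSO replicate 3. Of the values of named genes under the alternatives, 2712 kept their direction and side of the threshold, 214 were no longer past it, 3 were newly past it and 8 reversed. Each knocked-out transcript in its own clones kept its call with the other scaling, DESeq2, no filter, the serial run as a block and each library left out. With the clone as the replicate the parental control is a single sum, so that fit cannot weigh these calls. Where no construction is named below, the cause was not tested.

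Without the low-count filter, which adds genes to the test, leflunomide changed 957 genes, the overlaps with Drp1, Fis1 and Mff were 151, 70 and 195, 3 lists were called for Fis1, and 49 genes differed between genotypes. DESeq2 gave 740 genes for leflunomide, overlaps of 137, 60 and 173, and 321 genes between genotypes. A 2-fold minimum, which can only remove genes, left 607 in gs1B8, 1175 in gs2_B4, 1007 in gs1_B11, 834 in gs2_F6, 1088 in gs1_B4 and 1120 in gs1_C8. It left 302, 341 and 268 in both clones of Drp1, Fis1 and Mff, 24 in all 6 clones, 62 with leflunomide, and overlaps of 3, 3 and 8. The mean of both clones with libraries as replicates gave 6005, 5308 and 6217 genes. With the clone as the replicate the parental libraries form a single sum, so counts from that fit are not given. With libraries in place of clones as replicates, 9511 genes differed between genotypes, and 10007 with the serial run as a block, since the spread between clones then leaves the error. With the serial run as a block, 1 list was called for Fis1. All 27 libraries in 1 fit, which takes the smaller spread of the knockout arm into the error, gave 2532 genes for leflunomide, with Mfn1 (-0.127) and Dhodh (-0.243) newly past the threshold. Quality weights gave 2816 genes for leflunomide and turned Mff there to 0.037 from -0.018, neither past the threshold, while Fis1 there passed (0.315). With an estimated correlation 0 lists were called for Drp1, 0 for Mff and 0 for leflunomide. The test fry called 16, 9, 10 and 4 for Drp1, Fis1, Mff and leflunomide. Of the lists that camera called in both clones of a genotype, fry did not call MHC class I and the unfolded protein response for Drp1 or the interferon list for Mff. With leflunomide camera called 17 lists, so fry did not call most of them.

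Leaving out 1 library, which also lowers the number of samples, gave 3 to 6 lists for Drp1 (3 without parental replicate 1 or 3) and 0 to 3 for Fis1. The leflunomide count ran from 10 (without leflunomide replicate 2) to 1583 (without leflunomide replicate 3), with 13 and 26 without DMSO replicates 1 and 2, 166 without DMSO replicate 3, and 120 without leflunomide replicate 1. Its overlaps ran from 4 to 212 for Drp1, from 1 to 104 for Fis1 and from 2 to 256 for Mff. The Mff overlap is the lowest without leflunomide replicate 2, and the highest values come without leflunomide replicate 3. Reversals were of small means not past the threshold. Mfn2 in Mff KO clones ran from -0.018 (without parental replicate 3) to 0.113, and Dnm1l in Fis1 KO clones from -0.004 (without gs2_F6 replicate 3) to 0.058. Dnm1l under leflunomide ran from -0.031 to 0.014 and Mfn2 under leflunomide from -0.015 to 0.063, each reversed without leflunomide replicate 1. Opa1 under leflunomide ran from -0.095 to 0.03, with 0.03 and 0 without leflunomide replicates 1 and 2, and Mff under leflunomide from -0.052 to 0.042 (without DMSO replicate 2). Counts per clone, in both clones and in all 6 stayed within 1.5 times under leaving out 1 library, as did the numbers of lists of Mff and leflunomide, though not every list in them. No paired analysis was possible because the public titles number replicates but the columns carry none of those numbers. The serial run as a block rests on column order alone and gave 351 genes for leflunomide and 3208, 2377 and 2902 in both clones of Drp1, Fis1 and Mff. Depth was not varied. Of genes changed 1.5-fold in simulated data, 64.6% were recovered in a single clone and 48.0% in the drug arm, where the biological coefficients of variation were 6.80% and 15.3%.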

Other observations

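The test of a mixed parental culture was chosen only after the result was seen, and the genes and lists below were chosen after their values were seen. Cldn7, a claudin like Cldn3, had a mean of 12.7 CPM in parental cells and of 0 or 0.0121 CPM in the clones. The adhesion gene Epcam stood at 182 CPM in parental cells, fell to 152 CPM in gs1B8 and 168 CPM in gs2_F6 (adjusted p of 0.00023 and 0.03), and rose to 234 CPM in gs2_B4 and 284 CPM in gs1_B11 (adjusted p of 4.2e-06 and 1.4e-09). The cadherin gene Cdh1 stood at 375 CPM in parental cells and fell to 220 CPM in gs2_B4 and 247 CPM in gs1_B4 (adjusted p of 4e-08 and 1.1e-06). Vim, the mesenchymal intermediate filament gene, had 247 CPM in parental cells, 545 and 529 CPM in the Drp1 clones, 212 and 149 CPM in the Fis1 clones, 579 CPM in gs1_B4 and 7.60 CPM in gs1_C8. Bspry was at 8.37 CPM in parental cells, below 0.1 CPM in both Drp1 and both Fis1 clones, and at 2.18 and 14.6 CPM in the Mff clones.

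In gs1_C8, genes of cholesterol synthesis and cytosolic ribosomal proteins were lower together. Of 22 cholesterol synthesis and SREBP2 target genes 22 fell (22 adjusted over the list alone), with a median of -0.77 and an adjusted p of 3.9e-11 (adjusted p = 0.24 with an estimated correlation). Of 42 ribosomal protein genes 40 fell (41 adjusted over the list alone), with a median of -0.38 and an adjusted p of 1.5e-11 (adjusted p = 0.37 with an estimated correlation). Irf7, an interferon-induced transcription factor gene, stood at 65.2 CPM there against 1.45 CPM in parental cells. The interferon gene Ifnb1 stood at 0 CPM in parental cells and in the Drp1 and Fis1 clones, 0.0376 CPM in gs1_B4 and 0.13 CPM in gs1_C8. These values lie near the floor of 3 counts over the group (0.0373 CPM in gs1_B4 and 0.0388 CPM in gs1_C8), and the gene was not tested. Of 20 MHC class I genes 19 rose (19 adjusted over the list alone), with a median of 0.98 and an adjusted p of 6.5e-12 (adjusted p = 0.24 with an estimated correlation).

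Some genes were near 0 in some clones and present in others. Of 9637 genes above 5 CPM in parental cells, 23 were below 0.1 CPM in 1 to 5 clones, 2 (Cldn3 and Cldn7) in all 6, and 0 in the DMSO libraries. If the parental culture mixed cells with such a gene on and cells with it off, the clones that keep the gene should lie above the parental mean. Their median log2 ratio to parental was 0.16, above it for 15 of 23 genes, and at percentile 99.5 of 10000 random gene sets (median 0.01, highest 0.24). A mixed parental culture may therefore be a candidate explanation, but a weak one, since genes that vary more between clones also give a higher mean, and the random sets do not match that spread.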
